A study of Mus musculus with 6 samples.

How the data were processed

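RNA from lymphatic endothelial cells of mouse melanomas was measured in 6 libraries, 3 from mice that lack Ch25h in their lymphatic endothelium (Ch25h KO) and 3 from littermates that keep it (WT). Per the labels' protocols, tumours were digested with collagenases and DNase, cells negative for CD45 and positive for CD31 and GP38 were sorted, and cDNA was made with the SMART-Seq v4 kit, which copies full-length transcripts and does not mark their strand, before Nextera XT library preparation. Groups were taken from the genotype labels and library numbers from the sample titles. The titles of the Ch25h KO libraries carry the abbreviation HE, which the labels do not explain. Nothing in the labels says whether the 3 libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

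The deposited values are a normalized signal on the CPM scale of edgeR, 1 column per library, for 13454 genes named by symbol. Per the submitters' processing notes, STAR 2.7.0, HTSeq 0.9.1 and edgeR 3.26.8 were used with the mm10 genome build; the notes used here give no roles or order for these tools. The annotation, the strand setting of the counting and the rule by which genes entered the table are not given in the sources used here. The lowest mean over the 6 libraries of any gene in the table is 0.142 CPM. No mitochondrially encoded transcript is among the genes analysed here.

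Every value of a library was a whole multiple of its smallest value above 0, which was taken as the worth of 1 read. Divided by it, 100% of values were whole within 0.01 of a read. The recovered reads sum to between 36556824 and 46165273 per library. Normalization factors that edgeR computed by its TMM method on the recovered reads equalled those implied by the deposited columns, from 0.967 to 1.02, so the deposited values are CPM scaled by TMM factors. A single read was worth 0.0216 to 0.0268 CPM, and the limit that a count of 0 allows, 3 reads, lies between 0.0648 and 0.0805 CPM. SMART-Seq v4 reads carry no molecular identifiers, so intervals and limits cover only the error of counting reads. They are too narrow where several reads are copies of the same molecule.

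The main test was fixed before the data were examined: limma on log2(CPM + 1), with group as the only term, a variance prior with a trend and Benjamini-Hochberg adjustment, over the 11980 genes with a mean of at least 1 CPM, at a threshold of 0.05. Fold changes are Ch25h KO minus WT on that log2 scale, which understates the change of low genes. Means are given with SD and n = 3. An exact permutation test, two-sided, accompanies single values, and with 3 libraries against 3 it cannot go below p = 0.1.

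Fixed in advance were 26 gene lists covering sterol handling, lipid use, immune functions, endothelial identity, other cell types that the sort could carry, growth and stress. A list was tested with limma's camera, with a preset correlation of 0.01 and two-sided, if at least 4 members passed the filter, and 23 lists did. The correlation estimated from the data and limma's fry were alternatives, and the median of each list was also ranked among 10000 random lists matched on mean expression in 20 bins. Older symbols were resolved through RefSeq synonyms; among others, Msmo1 appears as Sc4mol, Ackr2 as Ccbp2, Ackr3 as Cxcr7 and Hbb-bs as Beta-s.

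Named genes follow a rule fixed in advance: Ch25h, the sort and lineage genes Pecam1, Pdpn, Ptprc and Prox1, in each direction the up to 12 genes of largest change past the threshold, filled up to 8 by smallest p where fewer than 5 qualified, and of each list up to 4 members past the threshold or else the 2 members of smallest p. Genes named by direction needed a mean of at least 5 CPM in the higher group, no overlap between the groups and a name other than that of a predicted gene, clone or pseudogene. Other genes named in the text were chosen after their values were seen.

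Alternatives were other pseudocounts, filters, scalings, variance priors, library weights, a block for the library number, edgeR's quasi-likelihood test and DESeq2 on the recovered reads, and leaving out each library. Tools were R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0. Gene positions are from GENCODE release M21 on the mm10 assembly, 1-based. It places 63 of the 64 named genes. Of these, 20 have exons that overlap exons of another annotated gene, 17 of them on the other strand. The kit does not mark strand, so strand could not tell apart reads from the overlapping stretches. Members of the H2, Gbp, Irgm and Tgtp families have close relatives, and how the counting treated reads that fit several of them is not given in the sources used here.

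The tests were checked on simulated data: reads were drawn for the listed genes at the libraries' own means, depths and spread, with 200 genes changed by known factors. In the simulated comparison of Ch25h KO with WT, limma ran on 11936 genes and called 56.7% of 67 genes changed 2-fold, 92.4% of 66 changed 4-fold and 98.5% of 66 changed 8-fold, with 0.102% of 11737 unchanged genes called. DESeq2 called 73.1% of 67 genes changed 2-fold and 0.37% of 13254 unchanged genes. For edgeR these shares were 58.2% and 0.0905%. When all cell cycle genes were simulated to rise by 1 on the log2 scale, camera called that list with the preset correlation (adjusted p = 1.16e-52) and with the estimated one (adjusted p = 0.0016), and 0 other lists with the preset one. Each simulated gene was drawn independently. The simulations therefore cannot tell how often lists are falsely called, or changed genes missed, where genes vary together between libraries.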

Results

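Lymphatic endothelial cells line lymphatic vessels, and here they were taken from B16-OVA-VEGFC melanomas. This transplanted mouse tumour line by its name carries VEGFC, a growth factor of lymphatic vessels. The recipients either lacked Ch25h in their lymphatic endothelium (Ch25h KO, 3 libraries) or were littermates with the gene intact (WT, 3 libraries). Ch25h encodes the enzyme that makes 25-hydroxycholesterol, an oxysterol that acts on sterol synthesis and on immune cells. The single comparison asks which transcripts of the tumour's lymphatic endothelium differ when the gene is missing there. The listed genes took 45952052, 41736922 and 46165273 reads in WT libraries 1, 2 and 3, and 36556824, 42542360 and 41016775 in Ch25h KO libraries 1, 2 and 3. Values are CPM scaled by TMM factors, and 11980 genes with a mean of at least 1 CPM were tested with limma on log2(CPM + 1). Pearson correlations of log values between libraries lay between 0.955 and 0.979, and every pair of libraries differed by more than sampling noise.

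Ch25h transcripts were nearly lost in the knockout libraries. The mean was 92.6 ± 12.1 CPM (SD, n = 3) in WT and 0.991 ± 1.70 CPM (SD, n = 3) in Ch25h KO, a log2 fold change of -5.87 ± 0.47 (SE; limma, adjusted p = 0.00365). The WT libraries held 3786, 3725 and 4913 reads of the gene. The knockout libraries held 0, 1 and 117 reads, with exact 95% Poisson intervals of 0 to 3.69, 0.0253 to 5.57 and 96.8 to 140 reads. Ch25h KO library 3 therefore kept Ch25h at 3.19% of the WT mean, 2.95 CPM. All WT values lay above all knockout values, and the exact permutation test gave p = 0.1, the smallest it allows here. Ch25h is a gene of a single exon on chromosome 19, at 34473778 to 34475164 on the minus strand of mm10, and it overlaps exons of the antisense transcript Gm26902. Where they overlap, strand could not tell reads of Gm26902 from those of Ch25h. The limma call was lost without WT library 1 (adjusted p = 0.0823) and with a pseudocount of 0.25 (adjusted p = 0.0779). The count models on recovered reads did not make it (adjusted p = 0.852 for edgeR and 0.211 for DESeq2). Over all 19 alternatives the adjusted p ran from 1e-05 to 0.852, and 15 of them made the call.

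**Figure D1:**
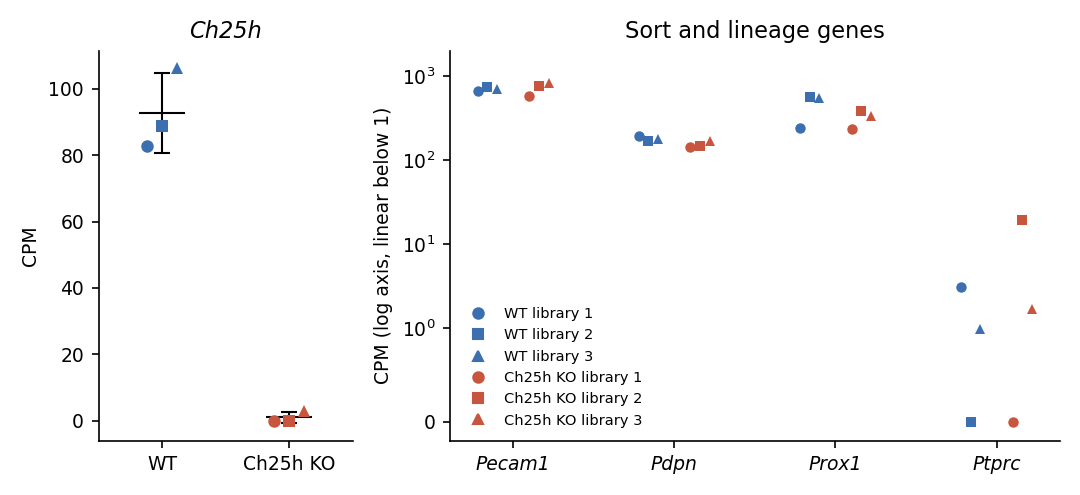
Normalized expression in CPM of Ch25h (left, linear axis) and of the sort and lineage genes Pecam1, Pdpn, Prox1 and Ptprc (right, log axis that is linear below 1 CPM) in each WT (blue) and Ch25h KO (red) library; horizontal lines and bars at Ch25h are group means and SD, n = 3. Ch25h lies at 82.9 CPM or above in every WT library and at 2.95 CPM or below in every Ch25h KO library, while Pecam1, Pdpn, Prox1 and Ptprc overlap between the groups.

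The genes behind the sort did not pass the test and overlapped between the genotypes. Pecam1, which encodes CD31, averaged 705 ± 38.8 CPM in WT and 723 ± 123 CPM in Ch25h KO (SD, n = 3; limma, adjusted p = 0.997). Pdpn, which encodes GP38, averaged 180 ± 11.5 CPM in WT and 155 ± 13.9 CPM in Ch25h KO (SD, n = 3; limma, adjusted p = 0.967). The lymphatic master regulator Prox1 averaged 451 ± 180 CPM in WT and 319 ± 77.8 CPM in Ch25h KO (SD, n = 3; limma, adjusted p = 0.973). Of the lymphatic identity list, 22 members were tested, 16 with a lower and 6 with a higher mean in Ch25h KO. Neither the list (median log2 fold change -0.13, camera adjusted p = 0.276; adjusted p = 0.773 with an estimated correlation) nor any member passed. Without Ch25h KO library 2 the list was called lower (median -0.20, adjusted p = 0.0366), while its median was -0.05 without Ch25h KO library 3 (adjusted p = 0.34) and -0.24 without WT library 1. Its members of smallest p were the connexin gene Gja4 (43.8 ± 26.8 CPM in WT, 19.5 ± 6.73 CPM in Ch25h KO) and Reln, which encodes reelin (392 ± 36.1 and 313 ± 21.1 CPM). The list of junction and pan-endothelial genes had a median of -0.07 over 20 members (camera adjusted p = 0.637). Erg, an endothelial transcription factor, averaged 44.4 ± 1.77 CPM in WT and 31.9 ± 3.54 CPM in Ch25h KO (limma, adjusted p = 0.836). Ptprc, which encodes the CD45 that was sorted against, was listed at 3.13, 0 and 0.994 CPM in WT libraries 1, 2 and 3 and at 0, 19.7 and 1.69 CPM in Ch25h KO libraries 1, 2 and 3.

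Markers of other cell types varied between libraries of the same genotype. The 16 leukocyte markers had a median log2 fold change of -0.67 (camera adjusted p = 0.425; adjusted p = 0.87 with an estimated correlation). Camera called them lower without WT library 2 (median -1.48, adjusted p = 3.58e-06) and without Ch25h KO library 2 (median -1.04, adjusted p = 0.00671), and without WT library 1 their median was 0.01. The score of the list, a mean log2 deviation from the WT mean, ran from -1.39 in WT library 2 to 1.01 in WT library 1. The complement gene C1qb of macrophages averaged 29.6 ± 29.3 CPM in WT and 8.11 ± 4.51 CPM in Ch25h KO (SD, n = 3). Medians were -0.42 over 11 fibroblast markers (camera adjusted p = 0.615; adjusted p = 0.874 with an estimated correlation) and 0.02 over 5 mural cell markers (camera adjusted p = 0.701). The fibroblast markers were called lower without WT library 2 (median -0.64, adjusted p = 0.000147), and without WT library 1 their median was 0.09. Melanocyte and melanoma markers rose as a list in Ch25h KO, with a median of 0.56, 12 of 14 members higher and a camera adjusted p of 0.00597. With an estimated correlation the call was lost (adjusted p = 0.773 with an estimated correlation), and 0 of the 14 members passed when adjusted over the list alone. For the list score the exact permutation test gave p = 0.4. The pigment enzyme gene Tyrp1 averaged 12.9 ± 8.43 CPM in WT and 24.4 ± 7.81 CPM in Ch25h KO (SD, n = 3). The list was no longer called without WT library 3 (adjusted p = 0.32) or without Ch25h KO library 1 (adjusted p = 0.481), nor at a mean of at least 5 CPM (adjusted p = 0.0718). Its median was 0.92 without WT library 1, 0.34 without WT library 2, 0.19 without WT library 3 and 0.26 without Ch25h KO library 1. The 4 tested red cell and platelet markers fell as a list (median -0.73, camera adjusted p = 0.0192; adjusted p = 0.773 with an estimated correlation), with Itga2b the single member that passed adjusted over the list alone. That call was lost without WT library 1 (adjusted p = 0.391) and without Ch25h KO library 1 (adjusted p = 0.0851), and the exact permutation test of the list score gave p = 0.2. Too few members passed the filter to test epithelial markers (1 member, Krt10), sex-linked genes (1 member, Xist, present in all 6 libraries) and mitochondrially encoded transcripts (0 members).

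Beyond Ch25h, no single gene passed the threshold over all genes. In limma 0 genes were higher and 1 was lower in Ch25h KO, and the next smallest adjusted p was 0.836. At an unadjusted p under 0.05 there were 648 genes, 194 higher and 454 lower, where chance gives 599. On the recovered reads edgeR called 0 genes, with 713 at an unadjusted p under 0.05, and DESeq2 called 17, 7 higher and 10 lower. In the simulation DESeq2 called 0.37% of 13254 unchanged genes and limma 0.102% of 11737, so some of the DESeq2 calls may be false. The unadjusted count was 1289 without WT library 1, 252 without WT library 3 and 417 without Ch25h KO library 3, and 1945 with library weights, where limma called 1 gene. Without WT library 1 limma called 0 genes, and without WT library 2 it called 1 higher and 2 lower. The groups did not overlap in 1218 genes, 10.2% of those tested, where chance gives 10%. On simulated data with the same depths and spread of single genes limma called 92.4% of genes changed 4-fold and 56.7% of genes changed 2-fold. Those genes were drawn independently, without variation shared between genes, so these shares do not show that such changes would be found here. The first principal component, 33.7% of the variance, placed WT library 3 at one end (-34.7) and Ch25h KO library 3 at the other (31.8).

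Among genes with no overlap between the groups, Vcam1, an adhesion molecule that binds leukocyte integrins, had the smallest p after Ch25h. It averaged 15.7 ± 10.2 CPM in WT and 1.77 ± 0.924 CPM in Ch25h KO (SD, n = 3), a log2 fold change of -2.46 ± 0.44 (SE; limma, adjusted p = 0.836; DESeq2, adjusted p = 1.37e-05). DESeq2 also called Neurl3 (3.86 ± 0.639 CPM in Ch25h KO, 16 ± 9.79 CPM in WT), the metalloprotease gene Adamts7 (50.8 ± 4.91 against 83 ± 7.02 CPM), Pik3r3, Plxdc1 and Tanc2 as lower. It did not call Cdh4 (adjusted p = 0.0983). Toward higher values in Ch25h KO stood Srpx2 (31.8 ± 10 CPM against 12.9 ± 1.29 CPM), Olfml2b, Cd2 and the secreted phosphoprotein gene Spp1 (707 ± 212 CPM against 371 ± 28.2 CPM), which DESeq2 called. Apln, Prss16, Enkur and Ezr stood in the same direction and were not called. Apln, which encodes the endothelial peptide apelin, averaged 58.5 ± 5.23 CPM in Ch25h KO and 26.7 ± 13.2 CPM in WT. Its log2 fold change was 1.20 ± 0.28 (SE), and without WT library 2 it was 1.57 and passed in limma (adjusted p = 0.0495). In limma none of these 15 genes passed over all genes, with an adjusted p of 0.836 for each.

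Antigen presentation genes were lower in Ch25h KO as a list. All 19 members had a lower mean, the median log2 fold change was -0.89, and camera gave an adjusted p of 2.63e-12. The members moved together from library to library, and the call was lost when that correlation was taken from the data (adjusted p = 0.773 with an estimated correlation). Adjusted over the list alone 10 of the 19 members fell, and adjusted over all genes in limma 0 did. The groups did not overlap in 9 members, where chance gives 10%: Nlrc5, the 7 MHC class II genes and Tapbp, named after its values were seen. The exact permutation test of the list score gave p = 0.2. The leukocyte marker score stood at 1.01, -1.39 and 0.38 in WT libraries 1, 2 and 3 and at -1.33, 0.63 and -0.25 in Ch25h KO libraries 1, 2 and 3. In the same order, the antigen presentation score stood at -0.14, -0.70 and 0.84 and at -1.04, -0.63 and -2.26, and the dissociation stress score at -0.25, -0.61 and 0.86 and at -0.64, -0.12 and 0.18. Nlrc5, the transactivator of MHC class I genes, averaged 90.8 ± 28.1 CPM in WT and 47.7 ± 12.6 CPM in Ch25h KO (SD, n = 3). H2-Ab1, an MHC class II chain, averaged 574 ± 504 CPM in WT and 107 ± 82.4 CPM in Ch25h KO (SD, n = 3), a log2 fold change of -2.51 ± 0.75 (SE). The MHC class II genes as a group were singled out after their values were seen. Log2 fold changes of H2-Aa, H2-Ab1, H2-Eb1, Cd74, Ciita, H2-DMa and H2-DMb1 lay between -2.60 and -2.13. The 11 class I and peptide loading genes lay between -0.92 and -0.23. WT library 3 and Ch25h KO library 3 held the extremes, with Cd74 at 3253 and 57.2 CPM. WT library 2 and Ch25h KO library 2 lay close together at 535 and 495 CPM. The median of the list was -0.58 without WT library 3, -0.49 without Ch25h KO library 3 and -0.24 without both, the last a setting chosen after seeing the data, and camera called the list in each of these.

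**Figure D2:**
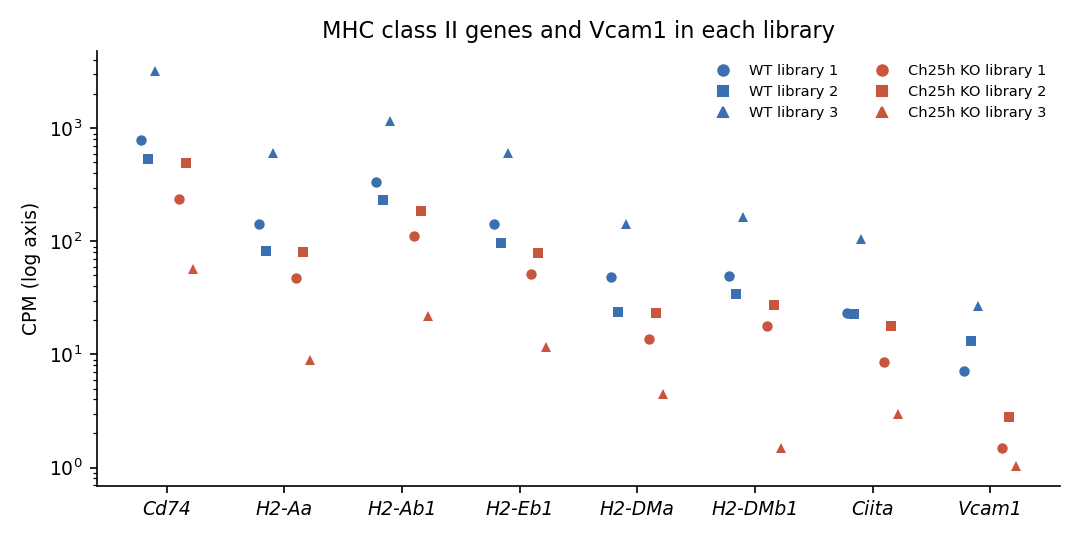
Normalized expression in CPM (log axis) of the 7 MHC class II genes and of Vcam1 in each WT (blue) and Ch25h KO (red) library; each point is 1 library. Every gene shown lies higher in all WT than in all Ch25h KO libraries, by little between WT library 2 and Ch25h KO library 2 for the class II genes (Cd74 at 535 and 495 CPM) and by most between the libraries numbered 3 (3253 and 57.2 CPM).

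Genes of leukocyte traffic were also lower as a list in Ch25h KO, with 22 of 28 members lower, a median of -0.37 and a camera adjusted p of 0.00266 (adjusted p = 0.773 with an estimated correlation). Adjusted over the list alone 4 members fell and 0 rose: Vcam1, the chemokine gene Ccl19 (19.2 ± 16.4 CPM in WT, 2.32 ± 1.78 CPM in Ch25h KO), and Selp and Cx3cl1, which encode P-selectin and fractalkine and were named after their values were seen. The lymphatic scavenger receptor Ackr3, listed as Cxcr7 and named after its values were seen, did not pass (limma, adjusted p = 0.836) and stood at 125, 80.8 and 62.9 CPM in WT libraries 1, 2 and 3 and at 134, 118 and 370 CPM in Ch25h KO libraries 1, 2 and 3. The list was not called without Ch25h KO library 1 (median -0.24, adjusted p = 0.0672), and its median was -0.22 without WT library 3. Its score stood at 0.03, -0.42 and 0.39 in WT libraries 1, 2 and 3 and at -0.74, -0.31 and -0.45 in Ch25h KO libraries 1, 2 and 3 (exact permutation p = 0.2). Within each genotype the library lowest in this score, WT library 2 and Ch25h KO library 1, was also the lowest in the leukocyte marker score (-1.39 and -1.33). Checkpoint and suppressive factors did not pass (median -0.28 over 12 members, camera adjusted p = 0.112; adjusted p = 0.773 with an estimated correlation). They were called lower without Ch25h KO library 3 (median -0.50, adjusted p = 0.0211) and without library 3 of both groups (adjusted p = 0.0186). Among them, Ido1, a tryptophan-degrading enzyme, averaged 11.8 ± 13.7 CPM in WT and 0.837 ± 0.663 CPM in Ch25h KO (SD, n = 3; limma, adjusted p = 0.836; DESeq2, adjusted p = 0.0028). Cd274, which encodes PD-L1, averaged 64.8 ± 47.8 and 20.9 ± 10.8 CPM. The interferon response list did not pass either (camera adjusted p = 0.146). Its 32 members went both ways, 16 lower and 16 higher, with a median of -0.04 and a mean of -0.33. Gbp2, an interferon-induced GTPase gene, averaged 921 ± 547 CPM in WT and 286 ± 148 CPM in Ch25h KO, and the transcription factor gene Irf1 averaged 430 ± 197 and 168 ± 71 CPM (SD, n = 3). With the preset correlation the interferon list was called lower without WT library 2 (adjusted p = 0.000287), without Ch25h KO library 1 (adjusted p = 0.00629), without Ch25h KO library 2 (adjusted p = 0.0132) and with quantile normalization (adjusted p = 0.0453), while with all libraries and an estimated correlation it was not (adjusted p = 0.87 with an estimated correlation). Its median was 0.14 without Ch25h KO library 3 (adjusted p = 0.617). The median of 18 NF-kB response genes was -0.17 (camera adjusted p = 0.338; adjusted p = 0.87 with an estimated correlation), with Traf1 at 39.7 ± 3.53 CPM in WT and 31.7 ± 3.86 CPM in Ch25h KO. Those genes were called lower without WT library 2 (median -0.31, adjusted p = 0.000903), and without WT library 3 their median was 0.01.

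Cholesterol synthesis genes and other targets of the sterol-regulated transcription factor SREBP2 rose slightly as a list in Ch25h KO. Of 25 members tested, 21 had a higher mean, the median log2 fold change was 0.25 and the camera adjusted p was 0.000594 (adjusted p = 0.773 with an estimated correlation). No member passed when adjusted over the list alone (0 of 25). Sqle, which encodes squalene epoxidase, averaged 124 ± 29.7 CPM in WT and 181 ± 32.5 CPM in Ch25h KO (SD, n = 3), and Fdps, which encodes farnesyl diphosphate synthase, 98.6 ± 22.4 and 133 ± 21 CPM. The list score was highest in Ch25h KO library 3 (0.51) and lowest in WT library 3 (-0.21). It was 0.05 and 0.16 in WT libraries 1 and 2 and 0.03 and 0.12 in Ch25h KO libraries 1 and 2. An exact permutation test of the score gave p = 0.5. The call was lost without WT library 3 (median 0.12, adjusted p = 0.0575) and without Ch25h KO library 3 (median 0.06, adjusted p = 0.246). Without both, a setting chosen after seeing the data, the median was -0.02 (adjusted p = 0.732). LXR targets, whose receptor oxysterols activate, had a median of -0.03 over 17 members (camera adjusted p = 0.52). The cholesterol exporter gene Abca1 averaged 107 ± 47.5 CPM in WT and 69 ± 31.7 CPM in Ch25h KO. The 18 genes of PPAR targets and fatty acid use had a median of -0.02 (camera adjusted p = 0.947). The lipase inhibitor gene Angptl4 averaged 308 ± 52.2 CPM in WT and 430 ± 58.2 CPM in Ch25h KO (SD, n = 3; limma, adjusted p = 0.836). In the list of oxysterol metabolism and sensing, 12 members, Ch25h was the single gene that passed, and the list did not (median -0.14, camera adjusted p = 0.362). Its median was -0.0037 without Ch25h KO library 1, -0.03 without WT library 3, and -0.08 without WT library 2 or without Ch25h KO library 3.

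**Figure D3:**
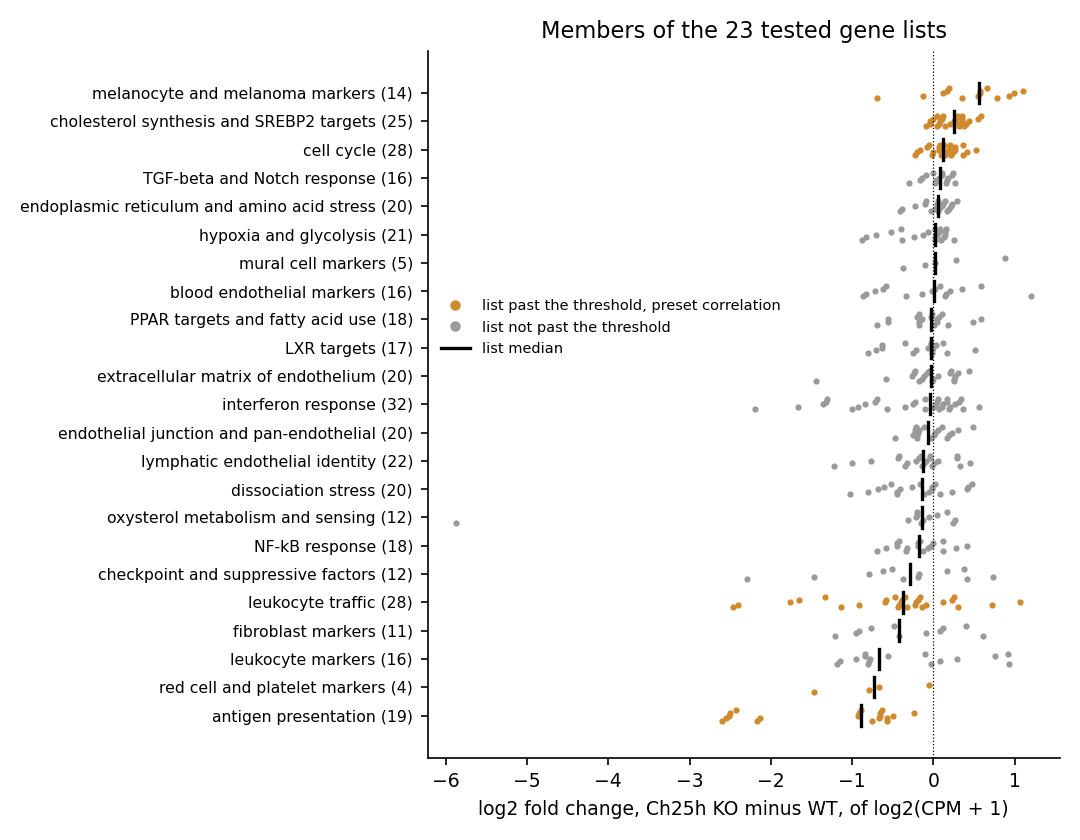
Log2 fold change (Ch25h KO minus WT, of log2(CPM + 1)) of every tested member of the 23 tested gene lists, with the number of members in brackets; black lines are list medians, and orange marks the 6 lists past the camera threshold with the preset correlation, none of which passed with an estimated correlation. Antigen presentation has the lowest median (-0.89), and the point near -5.87 is Ch25h.

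Cell cycle genes rose as a list by a small amount, with a median of 0.12, 21 of 28 members higher and a camera adjusted p of 0.00597 (adjusted p = 0.773 with an estimated correlation). No member passed adjusted over the list alone (0 of 28), and the exact permutation test of the list score gave p = 0.2. The mitotic genes Ccnb1 and Cdk1 averaged 28 ± 2.12 and 134 ± 12 CPM in WT and 37.5 ± 1.48 and 173 ± 15 CPM in Ch25h KO (SD, n = 3). The melanocyte and melanoma score stood at 0.74, -0.15 and -0.59 in WT libraries 1, 2 and 3 and at 0.87, 0.49 and -0.04 in Ch25h KO libraries 1, 2 and 3. In the same order, the cell cycle score stood at 0.01, 0.08 and -0.09 and at 0.19, 0.13 and 0.07. Like that of the melanocyte and melanoma markers, the call was lost without WT library 3 (adjusted p = 0.0897) and without Ch25h KO library 1 (median 0.07, adjusted p = 0.0851). The remaining lists did not pass with all libraries. The median was 0.01 over 16 blood endothelial markers and their mean -0.09, the direction of the test (camera adjusted p = 0.535). Adjusted over the list alone Apln rose and the arterial ligand gene Efnb2 fell (38.8 ± 5.24 CPM in WT, 21.6 ± 4.93 CPM in Ch25h KO). The 20 endothelial matrix genes had a median of -0.03 (camera adjusted p = 0.823; adjusted p = 0.954 with an estimated correlation), with the protease inhibitor gene Timp3 at 1145 ± 413 CPM in WT and 740 ± 155 CPM in Ch25h KO. They were called lower without library 3 of both groups (median -0.27, adjusted p = 0.0259). The 16 TGF-beta and Notch response genes had a median of 0.09 (camera adjusted p = 0.588). Hypoxia and glycolysis genes had a median of 0.02 and a mean of -0.14 over 21 members (camera adjusted p = 0.457, testing lower; adjusted p = 0.87 with an estimated correlation). They were called lower without WT library 3 (median -0.18, adjusted p = 0.00348). The glycolytic regulator gene Pfkfb3 averaged 195 ± 54.7 CPM in WT and 117 ± 7.83 CPM in Ch25h KO. Genes of endoplasmic reticulum and amino acid stress had a median of 0.06 (camera adjusted p = 0.431), and those of dissociation stress, which tissue digestion can induce, one of -0.14 (camera adjusted p = 0.441; adjusted p = 0.874 with an estimated correlation), each over 20 members. The dissociation stress score was highest in WT library 3 (0.86). Without that library the list was called higher (median 0.19, adjusted p = 0.00522), and it was called lower without WT library 2 (median -0.39, adjusted p = 0.001) and without Ch25h KO library 3 (median -0.30, adjusted p = 0.046). The immediate early gene Egr1 averaged 453 ± 410 CPM in WT and 211 ± 78.5 CPM in Ch25h KO (SD, n = 3).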

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

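The setting without library 3 of both groups was chosen after seeing the data; the other settings here were chosen before the data were examined. The count of genes past the threshold depended on the tool. All genes lower in Ch25h KO numbered 1 in the main limma test, 0 with a pseudocount of 0.25 and 0 in edgeR's quasi-likelihood test on recovered reads, and DESeq2 on the same reads called 10 lower and 7 higher; the cause was not tested. Leaving out each library in turn gave 0 to 1 genes higher and 0 to 2 lower. The Ch25h log2 fold change stayed below 0 in all 19 alternatives, from -7.26 to -4.05, and past the threshold in 15. It was -7.26 with a pseudocount of 0.25 (adjusted p = 0.0779), -6.55 in edgeR (adjusted p = 0.852) and -6.53 in DESeq2 (adjusted p = 0.211), and between -6.52 and -5.53 without each library, where the adjusted p ran from 1e-05 to 0.0823. The number of gene lists called was 6 in the main test, 0 with an estimated correlation, 0 with fry, 12 when medians were ranked among random lists, and 3 (without Ch25h KO library 1) to 10 (without WT library 2) when a library was left out. Random lists ignore that members vary together, which the correlation of 0.871 estimated for antigen presentation measures. Splitting the 6 libraries in all 10 ways gave at most 12 lists in a split other than the real one, and 5 of the splits gave at least 6; for genes past the threshold the real split gave 1 and the highest other split 0, and 1 of the splits gave as many. For antigen presentation, splits other than genotype gave medians of like size: the median was -0.87 (camera adjusted p = 6.9e-17) with WT libraries 1 and 3 and Ch25h KO library 2 against the rest, and -0.89 (adjusted p = 7.64e-07) with Ch25h KO library 1 in place of 2, against -0.89 (adjusted p = 2.63e-12) for the real split. With 10 splits no share under 0.05 can be reached. A split that set WT library 1 and Ch25h KO libraries 1 and 3 against the rest had 1657 genes at an unadjusted p under 0.05, against 648 for the real one. It was the highest count of all splits, singled out after the counts were seen, and its cause was not tested. With the library numbers as a replicate block, 0 genes were higher and 1 was lower (Ch25h, log2 fold change -5.87, adjusted p = 0.032) and 6 lists were called. Whether the numbers pair the libraries could not be told. Deviations from the group means correlated at 0.238, -0.0617 and -0.101 for same-numbered libraries, and by these deviations not every library correlated best with its own number. Pearson correlations of log values between the genotypes were 0.976 for the libraries numbered 1 and 0.979 for those numbered 2, the highest of all pairs. For the libraries numbered 3 the correlation was 0.955, the lowest of all pairs.

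Among single genes, signs turned for Pecam1, Dcn, Krt10 and Ptprc, which passed no test. Pecam1 was at -0.000417 with quantile normalization, -0.0835 without library 3 of both groups and between -0.0776 and 0.167 without each library. Dcn was at -0.054 and Krt10 at 0.245 without library 3 of both groups, and without each library Dcn ran from -0.0124 to 0.742, Krt10 from -0.456 to 0.0614 and Ptprc from -0.300 to 1.89. Over the named genes other than Ch25h, 1164 recomputed values kept direction and side of the threshold, 11 turned sign and 12 newly passed, 11 of them in DESeq2 and Apln without WT library 2.

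Of the list medians, those of the 6 called lists kept direction and side of the threshold in 59 recomputations and lost the threshold in 22, and cholesterol synthesis turned to -0.0193 without library 3 of both groups. Those of the 17 other lists kept both in 187, newly passed in 20 and turned sign in 31, some of which also passed. Without library 3 of both groups the turned medians were 0.187 (interferon response), -0.149 (blood endothelial), -0.0826 (mural cell) and -0.0867 (hypoxia and glycolysis), and with quantile normalization 0.0156 (PPAR targets). Without each library, medians that turned ran from -0.107 to 0.0154 (LXR targets), -0.133 to 0.0372 (PPAR targets), -0.228 to 0.14 (interferon response), -0.31 to 0.0103 (NF-kB response), -0.161 to 0.0556 (blood endothelial), -1.48 to 0.0111 (leukocyte markers), -0.641 to 0.0949 (fibroblast markers), -0.164 to 0.54 (mural cell), -0.176 to 0.0504 (hypoxia and glycolysis), -0.393 to 0.185 (dissociation stress), -0.24 to 0.13 (endothelial matrix) and -0.0585 to 0.231 (TGF-beta and Notch response). The causes were not tested. Red cell and platelet markers could not be tested at a mean CPM of at least 5 or without WT library 2, with fewer than 4 members left.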

Other observations

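The tests on interferon genes not looked at before and of a WT share mixed into a knockout library were fixed before their results were seen; the tests of leukocytes and other carried-over cells, of the libraries numbered 3, of paralogs and of cells that kept Ch25h were chosen only after the results they bear on had been seen. Single genes named here as examples were picked after their values were seen.

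The members of the interferon list, leaving out Parp14, Stat2, Bst2, Ifi35, Irf9 and Ifitm3, were sorted by the kind of interferon known to induce them. This was done after their values were seen, so the values of these sets are descriptive and their difference was not tested on these genes. The 9 genes known mainly as targets of interferon gamma, such as Gbp2, Irf1, Cxcl9 and Iigp1, all had a lower mean in Ch25h KO, with a median log2 fold change of -1.31, and the groups did not overlap in 3 of them. The 17 genes known mainly as targets of type I interferon, such as Ifit1, Isg15, Mx2 and Oas1a, had a median of 0.10, with 12 higher and 5 lower. A hypothesis was that lymphatic endothelium in Ch25h KO tumours received or answered less interferon gamma. It was put to genes outside every fixed list, but in the same libraries that had prompted it. Among 20 further interferon gamma targets, including Gbp4, Gbp5, Batf2, Socs1 and Irgm2, 19 had a lower mean and the median was -1.23, and among 25 further type I targets, including Oas2, Dhx58, Cmpk2 and Ifi204, the median was -0.13. Adjusted over the 20 genes alone 16 fell and 1 rose, Cd40. The score difference of these lists, gamma minus type I, was -0.45, -0.11 and 0.56 in the WT libraries and -1.05, -0.73 and -1.47 in the Ch25h KO libraries, without overlap (exact permutation p = 0.1, the smallest possible here).

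For the interferon gamma pattern, the difference of medians of -1.105 was past the bound of -0.5 set in advance for lower interferon gamma signalling. The score difference of -1.08 ± 0.37 (SE) was negative by more than 2 SE, as also required. The further genes were read in the same libraries as those already seen, with much the same interferon gamma scores. These were -0.41, -0.37 and 0.78 against -0.36, -0.445 and 0.80 in WT libraries 1, 2 and 3. In Ch25h KO libraries 1, 2 and 3 they were -0.97, -0.66 and -1.91 against -1.04, -0.61 and -2.07. The result thus largely restates the first pattern, and lower signalling remains a hypothesis that may account for it. Leukocytes that slipped through the CD45-negative sort stay open. Taking the leukocyte marker score as a covariate left the difference of scores at -1.07 ± 0.43 (SE). That marker score differed little between the genotypes, so the covariate could hardly move the difference. Its Ch25h KO mean was -0.32 relative to the WT mean, with an SD of 1.25 in WT (exact permutation p = 0.8). The marker score thus did not account for the difference, but leukocytes that it does not follow were not tested. Whether the libraries numbered 3 carry the difference stays open as well. Without both it was -0.61 ± 0.23 (SE) from 2 libraries per group, a spread that reaches past -0.5. The value met only a laxer bound than that asked of the antigen presentation genes, chosen after the results were seen. Reads shared between paralogs stay open: the 8 further interferon gamma targets without a close paralog had a median of -0.56 and a score difference of -0.75 ± 0.39 (SE), a spread that reaches past the bound of -0.5. Differences between animals or tumours, such as the number of interferon-producing cells around the vessels, were not tested.

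For the antigen presentation genes, which were likewise highest in WT library 3 and lowest in Ch25h KO library 3, leukocytes that passed the CD45-negative sort stay open. With the leukocyte marker score as a covariate the median log2 fold change was -0.86, against -0.89 without it, but the score difference of -1.22 had an SE of 0.71, and camera called the list with the preset correlation (adjusted p = 5.45e-12) and not with an estimated one (adjusted p = 0.779 with an estimated correlation). The covariate moved the leukocyte markers themselves from -0.67 to -0.22. It is the mean of these same markers, so a move toward 0 was set in advance and does not show that it follows leukocytes. Among the most abundant markers, Lyz2 averaged 83.9 ± 74.3 CPM in WT and 34.1 ± 24.4 CPM in Ch25h KO, and Cd14, 63.6 ± 7.43 and 62.5 ± 7.46 CPM. Whether the libraries at the extremes carry the list stays open too: without library 3 of both groups the median was -0.24, 17 of 19 members were lower, the MHC class II median was -0.87, and the score difference of -0.41 had an SE of 0.35 from 2 libraries per group. The criteria of both tests were made stricter after their values were seen, to require a margin of 1 SE; by the first criteria the leukocytes would have been argued against as the whole cause, and the libraries numbered 3 alone, with a median within 0.25 of 0, would have accounted for the list.

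The 117 reads of Ch25h in Ch25h KO library 3 set it apart from the other knockout libraries, which held 0 and 1. Melanoma cells that passed the sort are argued against, because 0 of 14 melanocyte and melanoma markers were highest in library 3 among the knockout libraries, and by their score 206.2 reads would be predicted in Ch25h KO library 1, where 0 were seen. For leukocytes and fibroblasts the scores likewise predict 234.2 and 140.3 reads in Ch25h KO library 2, where 1 was seen, which argues against cells of the same make-up in both libraries, but 3 of 16 and 3 of 11 of their markers, 6 in all, were highest in library 3 (Fcer1g at 200.1 CPM against 6.36 and 17.3 CPM, the largest exception), so a subset of these cells stays open. Endothelial cells that kept the gene, at 3.19% of the WT level if they express it as WT cells do, could not be tested, since no listed gene marks them. A share of a WT library mixed in also stays open, since 0 genes lay below the level that a mixture with WT library 1 or 2 would need, and 10 did for WT library 3.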
